A study of Mus musculus with 4 samples.

How the data were processed

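RNA of terminal end buds and ducts of the mouse mammary gland was hybridised to 4 single-colour arrays, 2 for each structure. Per the labels' protocols, RNA was extracted with TRI reagent and a column with DNase treatment, 1.5 microg of total RNA was used to make biotin-labelled cRNA, and ribosomal RNA was removed with magnetic beads. The deposited table holds one log2 value per Ensembl gene ID and array. Per the submitters' processing notes, the authors used RMA, a method that corrects background, normalizes probe intensities between arrays and summarises them on a log2 scale, and the genome build mm9. The version and settings of RMA, the array's annotation, any filter and the way values were formed per Ensembl ID are not given in the sources used here. The log2 scale was read from the range of the values, 1.15 to 14.9, and from the use of RMA. Scanner files and detection calls were not used here, so genes below background could not be set apart.

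The decimals of the deposited log2 values carry some information on how they were formed. For 8419 of the 28399 genes all 4 values have at most 5 decimals, and for 19913 they equal means of several numbers of 5 decimals (divisors up to 60, tolerance 0.005 units of the fifth decimal). No divisor was found for 67 genes. The divisor found is the smallest possible one, so it is a lower bound on how many numbers were averaged. Column medians differ between arrays, so the gene-level values are not quantile-normalized. How the averaging was done is not stated. Genes with at most 5 decimals, whose values show no averaging, have a larger spread between arrays than the other genes, which affects their test.

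Samples were grouped by their titles. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the deposited values of all 28399 IDs, with no block and no filter. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with at least a 1.5-fold change, and a floor of 2-fold was counted separately. The fit has 2 residual degrees of freedom, and limma's prior added 2.51. Separation by at least 2-fold without overlap was counted as a description that needs no variance model.

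The replicate numbers 1 and 2 occur in both groups. Deviations of same-numbered arrays from their group means correlated across genes with r = 0.086, and no label says that a number marks shared material. The numbers were therefore not treated as pairs.

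Before the data were examined, 36 gene lists of pathways and cell types, a panel of named genes and a rule for naming genes had been fixed by gene symbol. The rule took the 15 largest rises and falls past the call, the leading members of each list and the panel. None of it could be applied, because the deposited table gives IDs only. The reference table used here (RefSeq, GRCm38.p6) held no Ensembl IDs, so 0 of the 28399 IDs could be paired with a symbol. The design had also planned one probe set per symbol, and here each ID entered once. At most 2 IDs in each direction are therefore printed. Markers of fibroblasts, adipocytes, immune and other cell types were not analysed here for the same reason.

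In their place, 3 lists of Ensembl IDs were drawn from the mouse cell cycle marker pairs distributed with the R package scran, of which only the table of IDs was read. In each pair the first gene exceeds the second in a named phase. A gene entered a phase's list when it was the first member more often than the second for that phase and the second more often than the first for both other phases. The lists hold 97 G1, 83 S and 74 G2M genes, of which 96, 81 and 73 are measured. No gene is in more than one list. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the 3 lists. A list's median was also placed among those of 10000 random lists drawn from other genes within 20 bins of brightness. The marker pairs come from cultured cells and not from mammary tissue, and a list's name says which phase its genes mark there.

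Alternatives were quantile normalization, median centring, a filter on dim genes, a variance prior that follows brightness, robust moderation, treat, other thresholds, the replicate number as a block and leaving out each array in turn. The scripts were tested on simulated data with the real means and spreads of the 28399 genes and 200 changed genes. For the simulated comparison of terminal end bud with duct, the fit without a trend called 75 of 100 genes changed by 2 log2 units and 2 of 100 changed by 1 log2 unit, with 7 calls among unchanged genes. With the trend it called 77 and 4, with 6 calls among unchanged genes. A G2M list raised by 0.5 log2 units in simulated data was recovered with a median of 0.52. With no change its camera test gave an adjusted p of 0.67. As the simulated data were built from means and spreads, these results cannot show how camera behaves where genes of a list are correlated.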

Results

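Gene expression was measured in terminal end buds and in ducts of the pubertal mouse mammary gland. A terminal end bud is the bulbous growing tip that leads an elongating mammary duct at puberty, and the duct is the epithelial tube behind it. Both structures were freed from the fourth (inguinal) glands of C57/BL6 females by collagenase digestion and microdissection, and each sample represented about 300 to 400 structures. The labels give the age as 5 to 6 weeks in one place and as 6 to 7 weeks at killing in another. There were 2 terminal end bud arrays and 2 duct arrays, with one log2 value for each of 28399 Ensembl gene IDs. The submitters describe them as technical replicates from pooled material, so no p-value here says anything about variation between mice. P-values for single genes and from fry measure the spread between arrays. Those from camera and from the permutations of list membership rest on comparing genes with each other on the same arrays. Array data have no read depth, and their precision is limited by the number of arrays.

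The arrays of one structure resembled each other more than those of the other structure. The 2 terminal end bud arrays correlated across genes with Pearson's r = 0.979 and the 2 duct arrays with r = 0.968, and the 4 pairings of a terminal end bud with a duct array gave r between 0.948 and 0.961. These correlations are across genes, which are not independent replicates. The median absolute difference per gene was 0.21 log2 units between the terminal end bud arrays and 0.29 between the duct arrays, and it lay between 0.34 and 0.43 across structures. No pair of arrays was a copy, since at most 3 genes held the same value on any pair. The arrays were not on one scale. Medians were 6.41 and 6.35 on the terminal end bud arrays and 6.34 and 6.20 on the duct arrays, and the median gene was 0.11 log2 units higher in terminal end buds.

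The comparison of terminal end buds with ducts asks which transcripts separate the growing tip from the tube behind it. Between the structures, 2004 genes lay at least 2-fold apart with no overlap between arrays, 1258 of them higher in terminal end buds and 746 lower. The 2 other ways of splitting the 4 arrays into pairs gave 544 and 433 such genes, and 20 simulated comparisons with no change gave 187 to 269. A gene that separates the structures cannot separate the other splits, which lowers their counts. Both counts still exceeded the simulated ones, so the simulation did not hold all differences between these arrays. Between single arrays, 2855 to 4116 genes were at least 2-fold apart across structures, against 1333 between the terminal end bud arrays and 2250 between the duct arrays. After quantile normalization of the 4 arrays the split was 1009 higher and 971 lower, and after centring each array on its median it was 959 higher and 1027 lower. Counts without single arrays cannot be set against these, because no overlap is easier to reach with 1 array in a group. Among all genes, whatever the size of the difference, the structures did not overlap for 53.4%, where chance gives 33.3% with 2 arrays against 2. That share was counted on the deposited values only, where terminal end bud arrays have the higher medians, which can raise it. Genes share the same 4 arrays, so a split can lie off 33.3% without any difference between structures.

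No gene passed the test set for single genes, limma's moderated test with a Benjamini-Hochberg adjusted p under 0.05 and at least a 1.5-fold change. The smallest adjusted p from limma was 0.0657, shared by 126 genes. An unadjusted p under 0.05 was reached by 5604 genes, where 1420 would be expected by chance, and 3540 of these were higher in terminal end buds and 2064 lower. That majority depended on the scale of the arrays, with 2525 higher and 2870 lower after quantile normalization and 2653 higher and 2901 lower after median centring. Counts from fits without a single array are not set against the 5604, because each such fit leaves 1 array in a group. The count of 0 depended on how variance and dim genes were handled. When limma's prior variance followed brightness, 1485 genes passed, 1064 higher and 421 lower in terminal end buds. When genes below the median brightness were left out, 1426 passed, 974 higher and 452 lower, and 1121 genes passed in both of these fits. With the brightness trend on quantile-normalized values 1466 genes passed, 708 higher and 758 lower.

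Genes are given by Ensembl ID, because the reference table used here does not pair these IDs with symbols. The 4 IDs that follow were chosen after their values were seen, as the largest changes each way among genes that did not overlap and passed at 2-fold in the fit with a brightness trend. ENSMUSG00000022435 measured 11.66 ± 0.14 (SD, n = 2) in terminal end buds and 7.90 ± 0.17 (SD, n = 2) in ducts, a log2 difference of 3.76 with SE 0.20, or 13.6-fold. ENSMUSG00000047759 measured 7.92 ± 0.35 (SD, n = 2) in terminal end buds and 4.45 ± 0.57 (SD, n = 2) in ducts, which was 11.1-fold. In the other direction, ENSMUSG00000050944 stood at 4.68 ± 0.85 (SD, n = 2) in terminal end buds and 8.98 ± 0.68 (SD, n = 2) in ducts, a 19.8-fold difference. Its log2 difference of -4.31 was -4.91 without terminal end bud replicate 1 and -3.70 without terminal end bud replicate 2. ENSMUSG00000032496 stood at 6.79 ± 0.26 (SD, n = 2) in terminal end buds and 10.60 ± 0.18 (SD, n = 2) in ducts, which was 14.1-fold. The lower means of ENSMUSG00000047759 and ENSMUSG00000050944, 4.45 and 4.68, lie near the lower quartile of the arrays (4.48 to 4.53), where signal cannot be told from background without detection calls, so the size of these folds is uncertain. The adjusted p from limma was 0.0657 for ENSMUSG00000022435 and ENSMUSG00000032496, 0.0687 for ENSMUSG00000047759 and 0.0779 for ENSMUSG00000050944. In the fit with a brightness trend the adjusted p from limma was 0.0033, 0.0036, 0.0083 and 0.011 in that order. ENSMUSG00000047759 and ENSMUSG00000050944 belong to the genes whose 4 values have at most 5 decimals, and so show no averaging, a class with a larger spread between arrays.

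**Figure D1:**
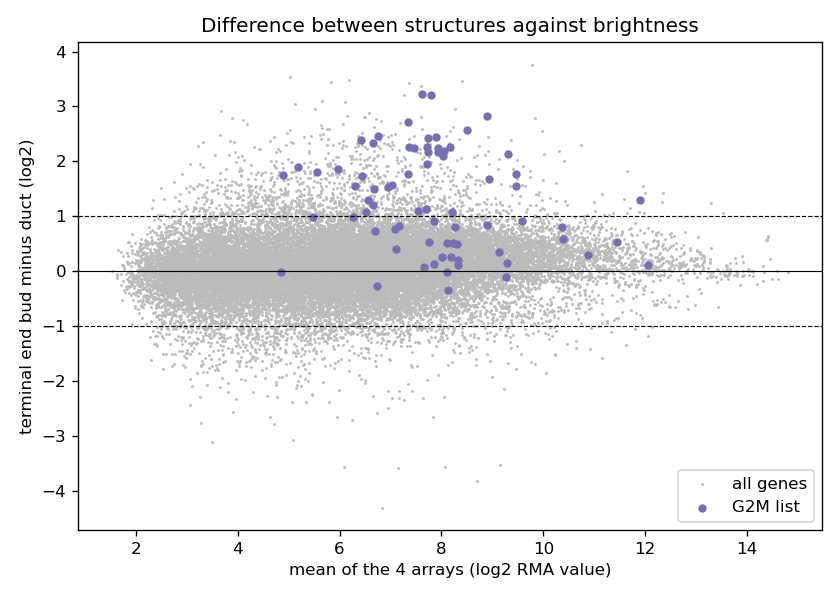
Each grey point is one of 28399 genes, with the mean log2 value of the 4 arrays on the x axis and the log2 difference, terminal end bud minus duct, on the y axis. Dashed lines mark 2-fold, and purple points are the 73 measured genes of the G2M list, of which 41 lie at or above the upper line and 0 at or below the lower line.

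Genes that mark the phases of the cell cycle lay higher in terminal end buds than in ducts, and those marking G2 and mitosis (the G2M list) stood furthest apart. The G2M list had a median difference of 1.21 log2 units, or 2.31-fold, and 68 of its 73 measured genes were higher in terminal end buds. Of these, 41 were at least 2-fold higher and 0 at least 2-fold lower, and the most changed member was 9.37-fold higher. The S phase list (genes marking DNA synthesis) had a median difference of 0.58, with 75 of 81 measured genes higher. The G1 list (genes marking the gap before DNA synthesis) had a median difference of 0.49, with 90 of 96 measured genes higher. These values include the offset between the structures, which was 0.11 for the median of all genes and larger at the brightness of these lists. Random lists matched on brightness had a median difference of 0.18 for G2M, 0.19 for S and 0.19 for G1. After quantile normalization the medians were 1.09 for G2M with 63 of 73 genes higher, 0.40 for S with 70 of 81 and 0.30 for G1 with 74 of 96. After median centring they were 1.09 for G2M with 65 genes higher, 0.47 for S with 70 and 0.37 for G1 with 82. On the deposited values, 4.65% of all genes were at least 2-fold higher in terminal end buds, against 56.2% of the G2M list, 27.2% of the S list and 16.7% of the G1 list.

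After subtraction of each array's median, the mean of the G2M list was 2.13 ± 0.05 (SD, n = 2) in terminal end buds and 0.95 ± 0.07 (SD, n = 2) in ducts. For the S list these means were 2.09 ± 0.04 (SD, n = 2) and 1.40 ± 0.07 (SD, n = 2), and for the G1 list 2.09 ± 0.07 (SD, n = 2) and 1.60 ± 0.07 (SD, n = 2). The gap between structures exceeded the spread between arrays for each list. With 2 arrays against 2, an exact permutation test of such a mean cannot go below p = 0.33 (two-sided).

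**Figure D2:**
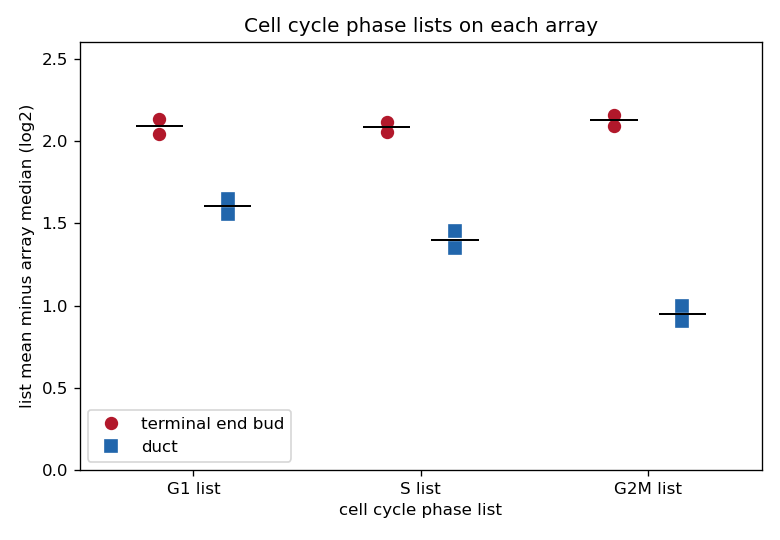
Each point is one array, with the mean log2 value of a cell cycle list minus that array's median on the y axis, and short black lines mark the mean of the 2 arrays. Within each list both terminal end bud arrays lie above both duct arrays, with means of 2.13 and 0.95 for the G2M list, 2.09 and 1.40 for the S list and 2.09 and 1.60 for the G1 list.

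Each list's shift was larger than that of the remaining genes by limma's camera test with a preset inter-gene correlation of 0.01. The adjusted p over the 3 lists was 4.1e-23 for G2M, 8.6e-15 for S and 1.2e-10 for G1. None of the 3 calls held when camera estimated the correlation, with adjusted p = 0.248 with an estimated correlation for each list on the deposited values. After median centring, adjusted p with an estimated correlation was 0.028 for G2M, 0.028 for S and 0.061 for G1, and after quantile normalization it was 0.066, 0.066 and 0.093. By limma's fry test, which asks whether a list's genes move one way on balance and does not compare them with other genes, adjusted p was 0.021 for G2M, 0.027 for S and 0.038 for G1. After median centring these were 0.0038, 0.0043 and 0.012. Each list's median lay above those of all 10000 random lists of the same size matched on brightness, whose central 95% ran from 0.07 to 0.29 for the G2M list. The G2M median exceeded the G1 median by 0.72, and a permutation test of list membership (two-sided, 100000 resamples) gave p = 1e-05, the smallest these permutations can give (adjusted p = 3e-05 over 3 comparisons of lists). It exceeded the S median by 0.62 (permutation p = 9e-04, adjusted p = 0.0014), and the S and G1 medians differed by 0.10 (permutation p = 0.07, adjusted p = 0.07). These permutations treat genes as independent, which they are not.

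At the level of single genes, 0 members of the 3 lists passed limma's test over all genes. Adjusted over the list alone, 48 G2M genes passed, all higher in terminal end buds. Such an adjustment is mild where most members have a small p, so these counts largely restate the shift of the list. Adjusted in the same way, 36 S genes passed higher and 2 lower, and 21 G1 genes passed higher and 0 lower. An unadjusted p from limma under 0.05 was reached by 53 of the 73 measured G2M genes, all of them higher. Among all 28399 genes it was reached by 5604. In the fit with a brightness trend over all genes, 39 G2M genes passed higher and 0 lower, against 27 higher and 1 lower for S and 24 higher and 1 lower for G1. Among all 28399 genes, 1485 passed in that fit. These counts are on the deposited values, where terminal end bud arrays have the higher medians. The phase lists were taken up after the gene IDs proved to be unnamed and before the values of their members were looked at.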

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

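The count of 0 called genes held under quantile normalization, median centring and robust moderation. Treat and no fold floor could only give 0, since the smallest adjusted p from limma was 0.0657 without any floor. Each fit without one array assumes that the lone array left varies like the other group, and cannot show whether the count is stable. The count of 0 moved to 1485 with a variance prior that follows brightness, to 1426 with genes above the median brightness only, to 549 at an adjusted p under 0.10 and to 1466 with the trend on quantile-normalized values, the last 2 chosen after seeing the data. Calls of at least 2-fold moved from 0 to 856, 682 and 858 with the trend, the brightness filter and the trend on quantile-normalized values. With the replicate number as a block, 0 genes were called and 5733 had an unadjusted p under 0.05, against 5604 without it, and no call changed. Among genes passing with the trend, 71.7% were higher in terminal end buds on the deposited values and 48.3% after quantile normalization, which moved the median of all genes from 0.11 to 0.0041. Genes with an unadjusted p under 0.05 numbered 2721 to 6291 without single arrays. Genes at least 2-fold apart without overlap numbered 2395 to 3318 without single arrays, the highest without duct replicate 1. These counts cannot be set against the 2004 with all 4 arrays, because no overlap is easier to reach with 1 array in a group. Among genes above the median brightness the count was 873, where fewer genes were tested. The list shifts relative to the median of all genes (1.1 for G2M, 0.48 for S and 0.38 for G1) lost their calls with an estimated correlation, at adjusted p = 0.248, and kept direction and call by camera under quantile normalization, median centring, the brightness filter, the replicate block and, without single arrays, at 1.11 to 1.18, 0.44 to 0.57 and 0.30 to 0.45. With an estimated correlation, 2 of the 3 calls (G2M and S) held after median centring and 0 after quantile normalization. On the deposited values camera estimated correlations of 0.28 for G2M, 0.35 for S and 0.32 for G1. After median centring these correlations were 0.038, 0.016 and 0.050, and after quantile normalization 0.062, 0.048 and 0.061. All of them exceeded the preset 0.01. The estimates thus fell when the arrays were put on one scale, and what remained of them was not tested for a cause. The 4 printed IDs kept their direction under each alternative run. The tests of the 36 symbol lists, the mean over probe sets, the fit of every probe set and lists without shared members were not run, since the table holds one unnamed value per gene. Without detection calls, the signal over background that limits dim genes is unknown.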

Other observations

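The tests on dim genes and on the scale of the 2-fold differences were chosen after the results they bear on had been seen, and the counts of genes without overlap and with a small unadjusted p were added after the files were read. The cell cycle lists and their tests were added after the files were read and before the values of their members were looked at, and the test on genes that show no averaging was set before its value was seen.

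Separation between the structures ran through most members of the cell cycle lists. Of the measured G2M genes, 62 of 73 were higher in terminal end buds with no overlap between arrays and 2 were lower with no overlap. For the S list 67 of 81 genes were higher without overlap and 4 lower, and for the G1 list 70 of 96 were higher and 4 lower. Of all genes 53.4% separated without overlap in either direction, where chance gives 33.3%. All these counts are on the deposited values. The share of all genes is not a matched comparison, since list genes were brighter, with medians of 7.79 to 8.10 against 6.31. Their median residual SDs were also smaller, 0.13 to 0.18 against 0.22.

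A higher share of dividing cells in terminal end buds is a candidate explanation for the G2M shift. A difference in array scale was argued against, since after quantile normalization the G2M median still lay 1.08 log2 units above that of all genes and at percentile 100 of the brightness-matched random lists, and so was the brightness of its genes, with percentile 100 on the deposited values. These percentiles treat genes as independent. With an estimated correlation, camera gave an adjusted p of 0.066 for G2M after quantile normalization. More dividing cells would raise the S list as well, and its median was at percentile 100 after quantile normalization. The G1 list, which was predicted to stay within its random lists, also lay above all of them, so more dividing cells cannot be told apart from a wider rise that takes in all 3 lists. A different share of other cell types in the dissected ducts was not tested.

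Although 5604 genes had an unadjusted p under 0.05, 0 passed after adjustment by limma, and uneven noise may account for this. The median residual SD was 0.312 in genes below the median brightness and 0.161 in those above it, a ratio of 1.94. Among genes above the median brightness, the 2957 genes whose values show no averaging had a median residual SD of 0.238 and the other genes 0.145, a ratio of 1.64. Below the median brightness these SDs were 0.440 and 0.259, so each difference was present at either level of the other. Such a range of variances goes with the 2.51 degrees of freedom of the single prior. In the simulated comparison with 4 arrays, 75 of 100 genes changed by 2 log2 units were called and 2 of 100 changed by 1 log2 unit. A brightness trend raised these simulated calls only to 77 and 4, whereas with genes below the median brightness left out, 50 of 50 and 14 of 50 were called. On the real arrays the fit without a trend called 0 genes, and the trend moved that count to 1485. The simulated data thus differed from the real arrays in how these fits behaved. Their counts cannot say how many real changes of either size were missed. The simulation did not vary the number of arrays, so its part was not tested.

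More genes were 2-fold higher than 2-fold lower in terminal end buds, 62.8% of the 2004 genes without overlap. After quantile normalization the share was 51.0%, so array scale may account for much of the excess. With the brightness trend on quantile-normalized values, genes called at 2-fold were 486 higher and 372 lower. Those called at 1.5-fold were 708 higher and 758 lower. Quantile normalization forces the arrays to one distribution and would also remove a real excess, and scale and biology cannot be told apart here.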
